A study of Mus musculus with 12 samples.

How the data were processed

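Total RNA of peritoneal macrophages from C57BL/6 mice was isolated with a column kit and made into Illumina libraries, per the labels' protocols. The 12 libraries were grouped by the genotype and treatment labels into 4 groups of 3. LPS dose and time, the strand setting, the read counter and its annotation are not given in the sources used here. The submitters' processing notes name the mouse build mm10 and the tools STAR, Cufflinks and Cuffdiff, without a role, order or version.

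The deposited table holds 53465 genes, of which 53274 identifiers are in GENCODE M21, and 112 entries share a symbol with another. Its values are a signal, judged from the values as deposited: a whole number of reads per gene divided by 1 factor per library and rounded to 1 decimal. No source used here records that division, which looks like median-of-ratios size factors. With a tolerance of 0.06 for rounding, 100% of the values in each of the 12 libraries were whole multiples of 1 step. A read was worth between 0.725 and 1.56 in the deposited values. The reads recovered in this way came to between 20489417 and 29354869 per library. The test had been planned for FPKM values, and the same log-scale test was used for these values.

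Genes with a value of at least 1 in at least 3 libraries were tested, which left 20419. Values were not rescaled. A limma trend model with 1 mean per group was fitted to log2(value + 1) over all 12 libraries, so the groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values from limma, and a gene was called below 0.05 with no minimum change. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. Folds are ratios of group means. Against a group at 0 in all 3 libraries a fold is a lower bound computed from a floor of 3 reads over the group. Against a group with 1 to 3 reads it carries an exact Poisson interval (95%), and such intervals and floors cover counting error only. The 5 contrasts were LPS in each genotype label, genotype label in each treatment, and their interaction.

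The test, the 33 gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Bhlhe40, Bhlhe41 and Lyz2. For each contrast it also took up to 10 genes per direction with the largest changes among called genes whose groups did not overlap between replicates (for the interaction, all called genes). These needed a mean of at least 1 in both groups or at least 5 in 1 group. Predicted gene models, clone names, histone, immunoglobulin, T cell receptor, small RNA and mitochondrial genes were left out. For each list described, up to 4 members with the largest changes were added, called ones first, and not every eligible gene is named. Some genes that the rule took are not reported here. Nos2, Il6 and Tnf between genotype labels with LPS fall outside the rule. Of the lists, 32 had at least 3 tested genes and went into 160 list tests with the camera function of limma at a preset correlation of 0.01, which called 87. With an estimated correlation 36 were called, all of them among the 87. The fry test of limma, which asks only whether a list moves on balance, called 132. Members were also counted with p-values adjusted over the list alone.

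Replicates of a group differed by more than the sampling noise of reads, with a chi-square per degree of freedom from 7.35 to 72.2 over 12 pairs and genes with at least 20 reads. None was therefore counted as a repeat sequencing of the same library. Whether they came from separate animals or cultures cannot be told from this spread. The main test was tested on simulated reads with 200 changed genes in 5 simulations per comparison. For LPS in Lyz2Cre (20606 genes) it recovered 52.4% of 2-fold and 68.4% of 4-fold changes, with 5.77% of calls false. For LPS in Lyz2Cre-BHLHE40-Fl (20608 genes) these values were 52.2%, 62.6% and 5.28%, and for genotype in controls (20605 genes) 50.2%, 64.8% and 3.69%. For genotype with LPS (20600 genes) they were 56.4%, 64.6% and 10.5%, and for the interaction (20620 genes) 44.8%, 54% and 5.18%. In the real data 18.8% (interaction) to 50.5% (LPS in Lyz2Cre-BHLHE40-Fl) of the tested genes were called, far more than the 200 changed here. These recovered and false shares therefore need not hold for the real contrasts. In simulated lists of 20 genes the camera test found the changed list in each of 5 contrasts and called 0 of 100 unchanged lists. Simulated genes were drawn independently and the changed lists held only genes raised 4-fold. False calls from correlation between the genes of a list were therefore not covered.

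Alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 5, median-of-ratios scaling, quantile normalization, robust variances, array weights, the 2 compared groups alone, the replicate number as a block, a minimum log2 change of 1, and each library left out in turn. Chosen after seeing the data were equal library totals, a mean of at least 50, and the count tests of edgeR and DESeq2 on the recovered reads. The interaction values of genes named for other contrasts were added to the alternatives then too. The edgeR test called 9507, 9866, 6651, 7111 and 4055 genes and the DESeq2 test 9344, 9676, 6415, 6887 and 3980, in the order of the contrasts above. Also chosen later were the tolerance of 0.06, the number of simulations, the minimum of 3 genes per list and the tests of edgeR, DESeq2 and camera on simulated data. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.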

Results

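RNA was sequenced from peritoneal macrophages, phagocytes of the abdominal cavity, of C57BL/6 mice at postnatal week 10. The 12 libraries fall into 4 groups of 3, a genotype label of Lyz2Cre or Lyz2Cre-BHLHE40-Fl crossed with a control or a lipopolysaccharide (LPS) treatment. Lyz2Cre stands for Cre recombinase driven from the lysozyme 2 locus, which is active in macrophages and other myeloid cells. BHLHE40 is a basic helix-loop-helix transcription factor that the series sets out to link to the inflammatory response of macrophages. LPS is a component of the outer membrane of Gram-negative bacteria that is sensed through TLR4, and its dose and time are not given in the sources used here. Each library held 20489417 to 29354869 reads assigned to genes. Values are reads divided by a factor per library, as deposited, and are given as mean ± SD with n = 3 libraries per group. The labels do not say whether replicates are separate cultures or animals, so the p-values measure only the spread between these samples.

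The deposited scaling gave mean totals per library of 22693602 in Lyz2Cre controls, 37605645 in Lyz2Cre with LPS, 20073802 in Lyz2Cre-BHLHE40-Fl controls and 30832914 in Lyz2Cre-BHLHE40-Fl with LPS. Bringing all libraries to equal totals moved the median log2 change of all genes from 0 to -0.58 for LPS in Lyz2Cre, from -0.05 to -0.56 for LPS in Lyz2Cre-BHLHE40-Fl, from 0.00 to 0.17 for genotype in controls and from -0.02 to 0.22 for genotype with LPS. Mitochondrial transcripts took 1.13% ± 0.214 of the reads in Lyz2Cre controls (SD, n = 3) and 0.562% ± 0.0655 in Lyz2Cre with LPS, with no overlap between libraries. In Lyz2Cre-BHLHE40-Fl they took 1.36% ± 0.233 in controls and 1.52% ± 0.662 with LPS, where replicate 1 had 0.756% and replicates 2 and 3 had 1.92% and 1.89%. Every Lyz2Cre-BHLHE40-Fl library with LPS was above the Lyz2Cre libraries with LPS, the highest of which had 0.600%. The leading principal component held 49.96% of the variance and the next 25.49%.

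**Figure D1:**
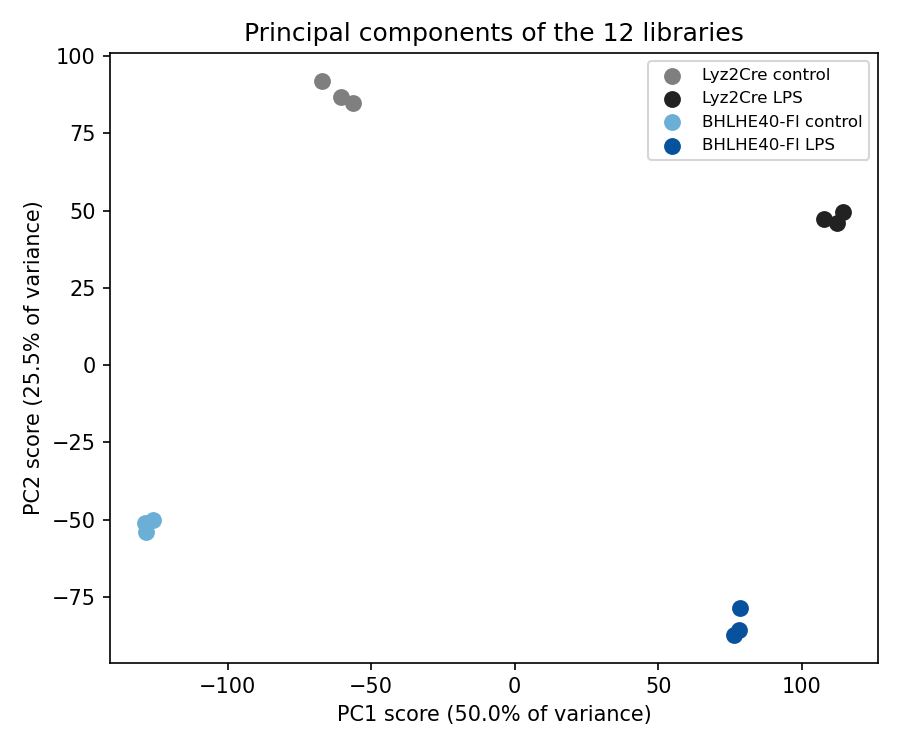
Scores of the 12 libraries on the leading principal components of log2(value + 1), PC1 (49.96% of the variance) against PC2 (25.49%), with 1 point per library coloured by group. The 4 groups lie apart, with the treatments separated on PC1 and the genotype labels on PC2.

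RNA of the targeted gene was not lower in the controls labelled Lyz2Cre-BHLHE40-Fl. Bhlhe40 (ENSMUSG00000030103, chromosome 6 from 108660629 to 108666925, plus strand, 5 exons, mm10) stood at 4976 ± 295 in Lyz2Cre controls and at 7893 ± 239 (SD, n = 3) in Lyz2Cre-BHLHE40-Fl controls, a log2 difference of 0.67 ± 0.08 (SE, limma adjusted p = 6.32e-06). With LPS it stood at 2467 ± 226 and 2232 ± 244, a log2 difference of -0.15 (limma adjusted p = 0.201) whose sign turned under equal library totals and under quantile normalization. In the 6 Lyz2Cre libraries it ranged from 2212 to 5306, and in the 6 libraries of the other label from 1956 to 8046. A value for the whole gene cannot show the loss of single exons, so this is no check of a partial deletion. The groups are therefore called libraries labelled Lyz2Cre-BHLHE40-Fl, or BHLHE40-Fl-labelled libraries, and every direction between genotypes below rests on that label. Bhlhe41, the close paralog, stood at 5335 ± 208 and 4661 ± 248 in controls (limma adjusted p = 0.232, and 0.0462 with the 2 compared groups alone) and was lower in BHLHE40-Fl-labelled libraries with LPS, at 2569 ± 498 against 3977 ± 485 (limma adjusted p = 0.000248). Lyz2, the lysozyme gene whose locus drives Cre, was lower in BHLHE40-Fl-labelled controls, at 170.2 ± 31.5 against 766 ± 69.8 (limma adjusted p = 1.2e-10). With LPS it stood at 769 ± 67.9 against 969.9 ± 56.2 (limma adjusted p = 0.0345), a call lost without Lyz2Cre LPS replicate 1 or 3 or without BHLHE40-Fl-labelled LPS replicate 2 or 3 (limma adjusted p = 0.0753, 0.118, 0.0663 and 0.147). It was also lost with no filter, quantile normalization and equal library totals (limma adjusted p = 0.0518, 0.156 and 0.785).

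**Figure D2:**
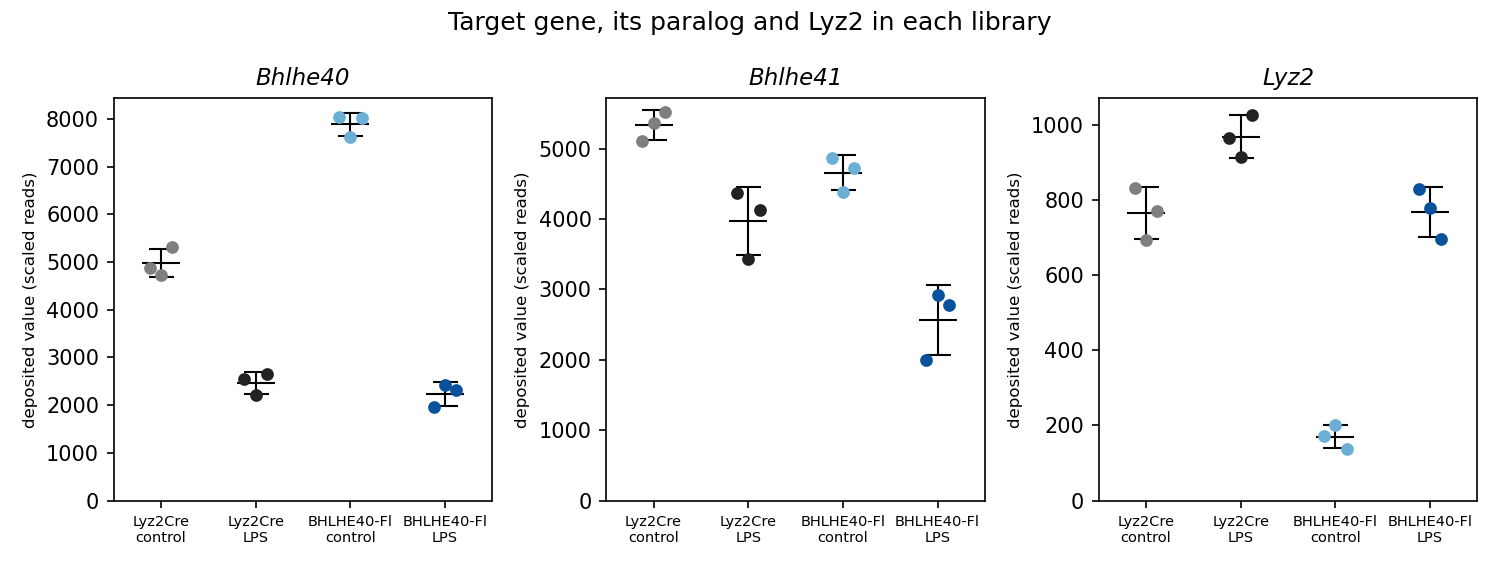
Deposited values (reads divided by a factor per library, linear axes from 0) of Bhlhe40, Bhlhe41 and Lyz2 in each of the 12 libraries. Points are libraries, horizontal bars are means and whiskers are ± 1 SD (n = 3); Bhlhe40 is not lower in the BHLHE40-Fl-labelled controls.

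The effect of LPS was first measured in the Lyz2Cre libraries. Cxcl10, an interferon-inducible chemokine, rose from 26.4 ± 13.2 to 114830 ± 8799.7 (SD, n = 3), or 4344-fold, and the cytokine gene Il6 from 17.1 ± 7.91 to 71584 ± 3823, or 4178-fold. Nos2, which encodes the inducible nitric oxide synthase, rose 197-fold to 152780 ± 8560.2, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 465 ± 83.1 to 209620 ± 19418. Il10, an anti-inflammatory cytokine gene, rose from 5.87 ± 0.961 to 654 ± 197. Cnr2, which encodes a cannabinoid receptor, fell from 894 ± 59.6 to 19.1 ± 2.74, and Arhgap19, a GTPase-activating protein gene, from 1211 ± 125 to 19 ± 6.58. The limma test called 5106 genes higher and 4871 lower of 20419, and 2760 and 2598 of these changed at least 2-fold. With equal library totals the higher genes made up 20.1% of the calls, against 51.2% with the deposited scaling. The mitochondrial share of reads was 1.13% in these controls and 0.562% with LPS.

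The inflammatory lists rose together in the Lyz2Cre libraries, where single values given for their members are log2 changes. The cytokine list had 19 of the 19 tested members higher (19 adjusted over the list alone, limma camera test, adjusted p = 1.57e-15), among them Il12a (log2 change 8.54) and Il27 (10.75). The chemokines had 18 of the 22 tested members higher and 2 lower (18 and 2 adjusted over the list alone, limma camera test, adjusted p = 1.76e-10), with Cxcl9 at 7.79 and Cxcl2 at 7.74. The inflammatory enzymes and mediators had 19 of the 22 tested members higher (19 adjusted over the list alone, limma camera test, adjusted p = 5.39e-15). The costimulatory receptor gene Cd40 stood at 7.66. Genes of the NF-kB pathway and its feedback had 21 of the 22 tested members higher (21 adjusted over the list alone, limma camera test, adjusted p = 5.12e-17). Traf1 stood at 4.83, the cytokine signalling inhibitor Socs3 at 4.81 and the NF-kB inhibitor Nfkbia at 4.22. Interferon-stimulated genes had 44 of the 44 tested members higher (44 adjusted over the list alone, limma camera test, adjusted p = 2.41e-25, and adjusted p = 0.148 with an estimated correlation). The antiviral genes Rsad2, Cmpk2 and Mx1 changed by 7.32, 8.45 and 7.41 on the log2 scale. Genes of MHC class I presentation had 18 of the 18 tested members higher (18 adjusted over the list alone, limma camera test, adjusted p = 7.94e-12, and adjusted p = 0.117 with an estimated correlation). The peptide transporter gene Tap1 stood at 3.27 and the MHC class I transactivator gene Nlrc5 at 3.28. The TLR4 receptor pathway had 13 of the 21 tested members higher and 4 lower (13 and 4 adjusted over the list alone, limma camera test, adjusted p = 0.00172), and with equal library totals it had 6 higher and 11 lower and was not called (adjusted p = 0.213). Its adaptor gene Myd88 changed by 2.66 and the LPS co-receptor gene Cd14 by 1.95.

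The lists of cholesterol synthesis, cell cycle and clock genes were lower after LPS in the Lyz2Cre libraries. Cholesterol synthesis had 3 of the 24 tested members higher and 17 lower (3 and 18 adjusted over the list alone, limma camera test, adjusted p = 1.88e-05, and adjusted p = 0.0827 with an estimated correlation). Dhcr7, the last reductase of the pathway, fell from 650.2 ± 19.7 to 74.9 ± 16.1 and the sterol carrier gene Stard4 from 740.1 ± 27.8 to 184 ± 30.1 (SD, n = 3). The cell cycle list had 6 of the 34 tested members higher and 23 lower (6 and 24 adjusted over the list alone, limma camera test, adjusted p = 0.000827, and adjusted p = 0.2 with an estimated correlation). Ccna2, which encodes cyclin A2, fell from 261 ± 45.3 to 65 ± 7.15 and the replication helicase gene Mcm2 from 461 ± 5.83 to 121 ± 10.4, whereas the spindle gene Tpx2 rose from 365 ± 37.5 to 1534 ± 70.7. The circadian clock list had 1 of the 17 tested members higher and 11 lower (1 and 11 adjusted over the list alone, limma camera test, adjusted p = 0.00135, and adjusted p = 0.117 with an estimated correlation). Its members Dbp, Tef and Per3 changed by -3.29, -3.12 and -2.81 on the log2 scale. Bhlhe40 itself fell from 4976 to 2467, a log2 change of -1.01 (limma adjusted p = 1.24e-08), and Bhlhe41 changed by -0.43 (limma adjusted p = 0.00463). For Lyz2 the log2 change of 0.34 (limma adjusted p = 0.0243) became -0.38 with equal library totals. The call was lost with quantile normalization (limma adjusted p = 0.166) and without Lyz2Cre control replicate 2 or Lyz2Cre LPS replicate 1 or 3 (limma adjusted p = 0.107, 0.0556 and 0.0898).

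In the BHLHE40-Fl-labelled libraries LPS raised many of the inflammatory genes from levels near 0. Il1b, the gene of interleukin 1 beta, rose from 2.43 ± 2.92 to 84193 ± 5549 (SD, n = 3), and Acod1, whose enzyme makes itaconate, rose 9672-fold from 17 ± 11.7 to 164420 ± 6886. The chemokine gene Ccl5 rose from 0.733 ± 0.751 to 27720 ± 8811 (37800-fold, counting interval 12697 to 179930), and Nos2 from 0.533 ± 0.924 to 11002 ± 1764 (20630-fold, counting interval 6116 to 182420). Il6 rose 22530-fold to 27787 ± 2898, Cxcl10 reached 138530 ± 3575 and Il12b, a subunit gene of interleukins 12 and 23, reached 7999.9 ± 508. Rab7b, an endosomal GTPase gene, fell from 12849 ± 420.0 to 263 ± 23.7 and the chemokine receptor gene Cxcr4 from 3699 ± 208 to 80.2 ± 10.5. On the log2 scale Cnr2 changed by -6.72 and Arhgap19 by -5.57. The limma test called 5086 genes higher and 5234 lower, of which 2673 and 2939 changed at least 2-fold. With equal library totals the higher genes made up 21.5% of the calls, against 49.3%.

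The inflammatory lists rose in the BHLHE40-Fl-labelled libraries too, and single values are again log2 changes. The cytokines had 19 of the 19 tested members higher (19 adjusted over the list alone, limma camera test, adjusted p = 5.14e-18) and the chemokines 20 of the 22 tested members higher and 2 lower (20 and 2 adjusted over the list alone, limma camera test, adjusted p = 3.7e-14), with Cxcl9 at 0 in all 3 controls and at least 3068-fold higher with LPS. Inflammatory enzymes and mediators had 22 of the 22 tested members higher (22 adjusted over the list alone, limma camera test, adjusted p = 6.18e-21). Cd40 stood at 10.72. The NF-kB list had 22 of the 22 tested members higher (22 adjusted over the list alone, limma camera test, adjusted p = 8.95e-20). Nfkbiz stood at 6.12 and Socs3 at 6.29. Interferon-stimulated genes had 44 of the 44 tested members higher (44 adjusted over the list alone, limma camera test, adjusted p = 2.04e-32, and adjusted p = 0.116 with an estimated correlation). Gbp5 stood at 12.31, Mx1 at 12.28 and Ifit3 at 11.86. MHC class I presentation had 18 of the 18 tested members higher (18 adjusted over the list alone, limma camera test, adjusted p = 4.67e-15, and adjusted p = 0.093 with an estimated correlation). Nlrc5 stood at 5.62 and Tap1 at 5.33. Immediate early genes had 17 of the 23 tested members higher and 2 lower (17 and 2 adjusted over the list alone, limma camera test, adjusted p = 7.35e-05, and adjusted p = 0.0731 with an estimated correlation), among them the nuclear receptor gene Nr4a3 at 7.14 and Ier3 at 4.08. The clock list had 0 of the 17 tested members higher and 13 lower (1 and 13 adjusted over the list alone, limma camera test, adjusted p = 0.000125, and adjusted p = 0.0876 with an estimated correlation). Dbp stood at -4.46 and Tef at -3.15.

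Cholesterol synthesis and cell cycle genes did not pass as lists for LPS in the BHLHE40-Fl-labelled libraries. Cholesterol synthesis had 9 of the 24 tested members higher and 8 lower (10 and 8 adjusted over the list alone, limma camera test, adjusted p = 0.813). Dhcr7 fell from 327 ± 27.5 to 60.5 ± 8.81 (SD, n = 3). The cell cycle list had 8 of the 34 tested members higher and 14 lower (8 and 15 adjusted over the list alone, limma camera test, adjusted p = 0.428). Within it the cyclin E1 gene Ccne1 rose from 78 ± 2.31 to 599 ± 43.8 and the proliferation marker Mki67 from 594 ± 52.1 to 2167 ± 132. Bhlhe40 fell by 1.83 on the log2 scale (limma adjusted p = 2.72e-12), Bhlhe41 by 0.88 (limma adjusted p = 4.25e-06), and Lyz2 rose by 2.18 (limma adjusted p = 2.98e-11). No libraries are shared between the LPS comparisons of the genotype labels. Across genes their log2 changes correlated with Pearson r = 0.798, genes not being independent replicates. Both comparisons called 3907 genes higher and 3591 lower, where independent lists would share 1272 and 1249, and 280 were called in opposite directions.

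**Figure D3:**
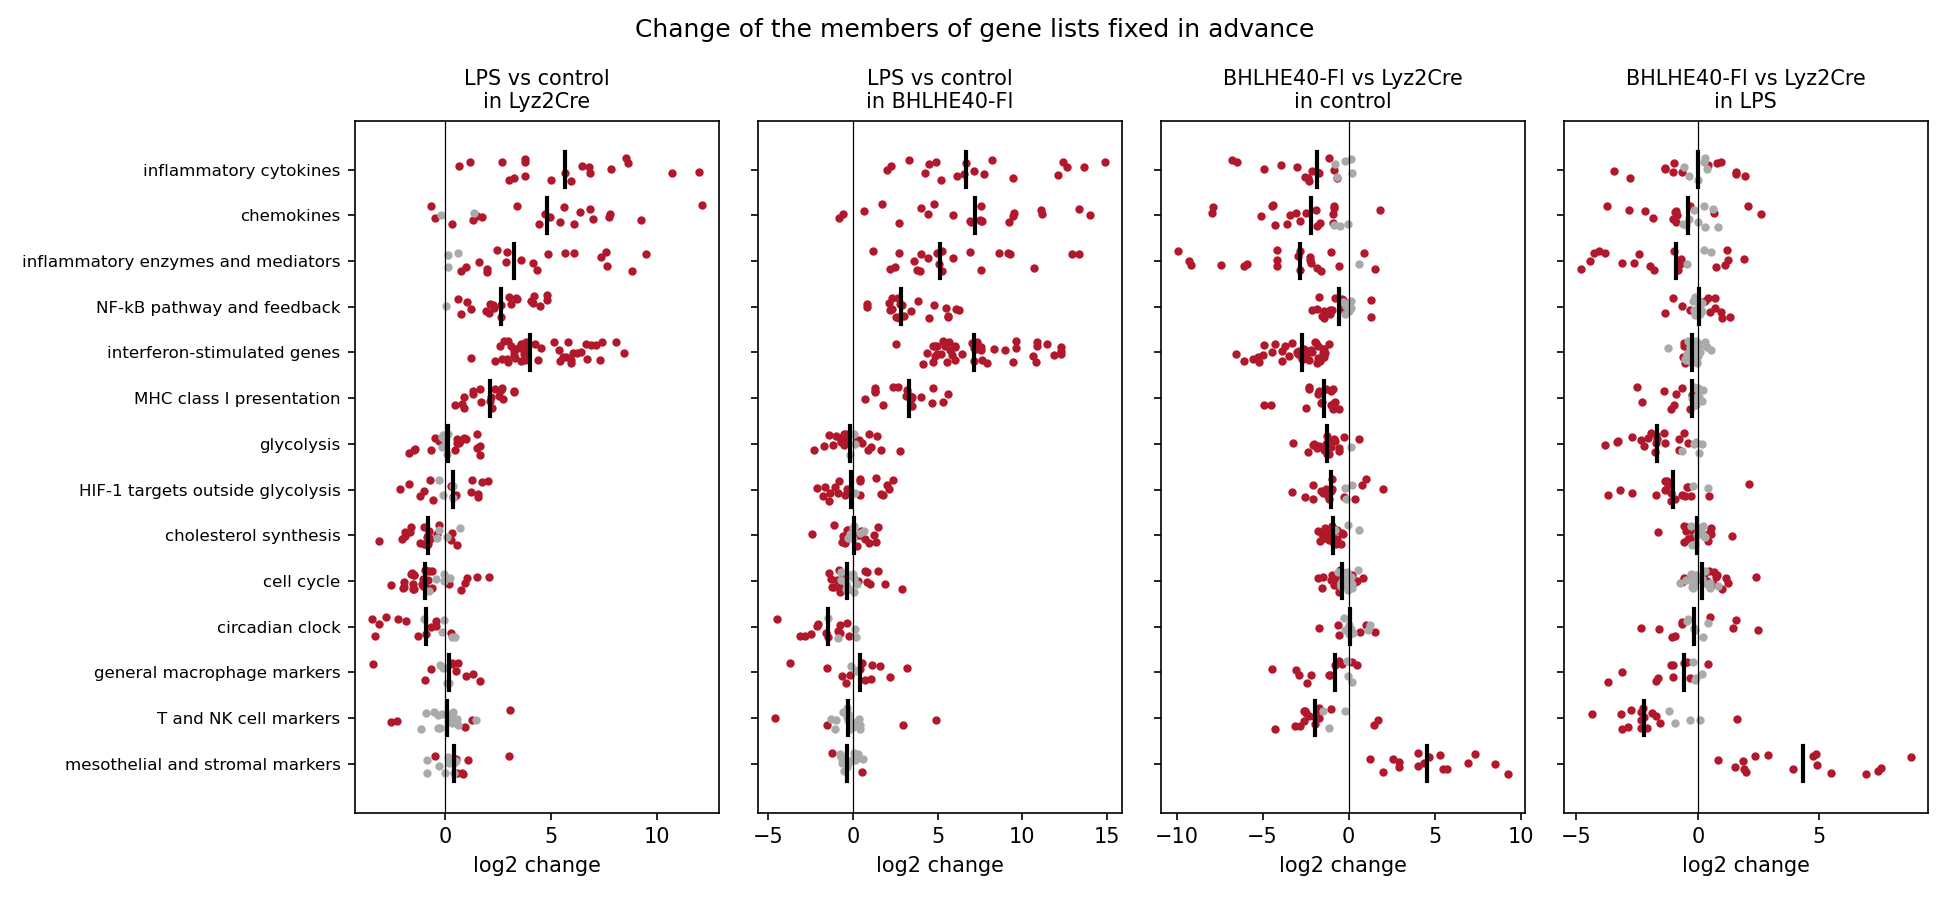
Log2 change of each tested member of 14 gene lists (rows) in the 4 comparisons (panels, each with its own x axis). Red points passed the limma test at adjusted p below 0.05, grey points did not, and black bars are list medians; the interferon-stimulated genes have a median of -2.68 between genotype labels in controls and -0.23 with LPS, where quantile normalization gives 0.14 and equal library totals 0.060.

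Without LPS, the libraries of the genotype labels differed in inflammatory genes and in genes of mesothelium. In BHLHE40-Fl-labelled controls Acod1 stood at 17 ± 11.7 against 9899 ± 1268 in Lyz2Cre controls (SD, n = 3), and the siderophore-binding lipocalin gene Lcn2 at 8.03 ± 6.09 against 7451 ± 607. Nos2 was lower (1457-fold, counting interval 432 to 12884), as were Ccl5 (566-fold, counting interval 189.9 to 2692) and the acute-phase gene Orm1 (4191-fold, counting interval 705 to 155130). Fpr2, a receptor gene for formyl peptides, was at 0 in all 3 BHLHE40-Fl-labelled controls, at least 1049-fold lower, and haptoglobin (Hp) was at 34 ± 1.97 against 11634 ± 1215. The monocyte gene Ly6c2 was at 0.5 ± 0.436 against 1217 ± 164, and since it has close copies its reads are uncertain. In the other direction Upk3b, a uroplakin gene of mesothelium, was at 0 in all 6 Lyz2Cre libraries and at 629 ± 153 in BHLHE40-Fl-labelled controls, at least 780.1-fold higher. Gata6, a transcription factor gene of resident peritoneal macrophages, was higher at 333 ± 39.9 against 24.7 ± 9.06. Its value is not split by cell type, and genes of mesothelium were higher in the same libraries. The cells that held the Gata6 RNA therefore cannot be told. The list of large peritoneal macrophage markers had 6 of the 26 tested members higher and 14 lower (6 and 15 adjusted over the list alone, limma camera test, adjusted p = 0.00229). The limma test called 3060 genes higher and 3385 lower, of which 1608 and 1509 differed at least 2-fold. With equal library totals the higher genes made up 66.9% of the calls, against 47.5%.

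Inflammatory and interferon lists were lower in BHLHE40-Fl-labelled controls, in which mesothelial and stromal markers were higher (median log2 difference 4.56) and general macrophage markers lower (-0.77). Single values are log2 differences. Interferon-stimulated genes had 44 of the 44 tested members lower (44 adjusted over the list alone, limma camera test, adjusted p = 2.33e-31, and adjusted p = 0.117 with an estimated correlation). Ifi44 stood at -6.56, Ifit3 at -6.09 and Ifit2 at -5.25. These genes varied between the Lyz2Cre controls, where Ifit3 was 832 in replicate 1, 2510 in replicate 2 and 275 in replicate 3, all above its highest BHLHE40-Fl-labelled control of 15.9. Inflammatory enzymes and mediators had 2 of the 22 tested members higher and 19 lower (2 and 19 adjusted over the list alone, limma camera test, adjusted p = 1.38e-19). The serum amyloid gene Saa3 stood at -6.06. Chemokines had 1 of the 22 tested members higher and 18 lower (1 and 18 adjusted over the list alone, limma camera test, adjusted p = 1.1e-14). Cxcl3 stood at -7.91. Cytokines had 14 of the 19 tested members lower (14 adjusted over the list alone, limma camera test, adjusted p = 9.8e-11). The activin gene Inhba stood at -6.80 and Il1b at -6.49. MHC class I presentation had 18 of the 18 tested members lower (18 adjusted over the list alone, limma camera test, adjusted p = 1.64e-17, and adjusted p = 0.0736 with an estimated correlation). H2-K1 stood at -2.31 and Nlrc5 at -2.49. Lists that the camera test did not call higher for LPS in Lyz2Cre were lower too. Among them glycolysis passed the fry test for that LPS effect (adjusted p = 1.08e-05), with a mean log2 change of 0.22. Glycolysis had 1 of the 23 tested members higher and 21 lower (1 and 21 adjusted over the list alone, limma camera test, adjusted p = 1.03e-16). Aldoc stood at -3.21, the lactate transporter gene Slc16a3 at -2.35 and the phosphofructokinase gene Pfkl at -2.09. Cholesterol synthesis had 21 of the 24 tested members lower (22 adjusted over the list alone, limma camera test, adjusted p = 4.27e-14). Sqle stood at -1.75. The alternative activation list had 4 of the 20 tested members higher and 11 lower (4 and 13 adjusted over the list alone, limma camera test, adjusted p = 0.000482). Arginase 1 (Arg1) stood at -4.88 and the transglutaminase gene Tgm2 at -3.06. For LPS in Lyz2Cre the fry test called this list higher (adjusted p = 0.0261). Deposited values of Tgm2 there were 24096 to 26480 in controls and 45785 to 47827 with LPS.

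Markers of cell types moved with the genotype label. All 16 mesothelial and stromal markers were higher in BHLHE40-Fl-labelled controls (16 adjusted over the list alone, limma camera test, adjusted p = 1.32e-18), with Lrrn4 759.9-fold, counting interval 258 to 3658, Krt19 309.6-fold, counting interval 90.4 to 2696 and Upk1b at 295 ± 29.1 against 1.07 ± 1.22 (SD, n = 3). General macrophage markers had 2 of the 15 tested members higher and 10 lower (2 and 10 adjusted over the list alone, limma camera test, adjusted p = 2.04e-06). Itgam, which encodes CD11b, was lower at 1179 ± 84.9 against 9696 ± 234, Adgre1, which encodes F4/80, at 5635 ± 245 against 30456 ± 725, and Aif1 at 22.7 ± 1.71 against 515 ± 76.2. Small peritoneal macrophage and monocyte markers had 1 of the 17 tested members higher and 13 lower (1 and 13 adjusted over the list alone, limma camera test, adjusted p = 1.67e-09). Cx3cr1 stood at a log2 difference of -5.18 and the Fc receptor gene Fcgr1 at -2.89. T and NK cell markers had 2 of the 19 tested members higher and 14 lower (2 and 15 adjusted over the list alone, limma camera test, adjusted p = 0.00845, and adjusted p = 0.0581 with an estimated correlation), and Cd3g stood at 31.2 ± 8.47 in Lyz2Cre controls against 0.767 ± 0.802. Neutrophil markers had 3 of the 9 tested members higher and 5 lower (3 and 5 adjusted over the list alone, limma camera test, adjusted p = 0.0607), and the list was called without BHLHE40-Fl-labelled control replicate 1 or 3 (adjusted p = 0.0299 and 0.0386) and with equal library totals (adjusted p = 0.0214). The neutrophil collagenase gene Mmp8 was at 24800 ± 2140.1 in Lyz2Cre controls against 366 ± 106.

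With LPS, several inflammatory genes stayed lower in the BHLHE40-Fl-labelled libraries while others were higher. Hp stood at 152 ± 33.3 against 10864 ± 806 in the Lyz2Cre libraries with LPS (SD, n = 3), Mmp8 at 206 ± 7.68 against 14408 ± 209.9, Orm1 at 8 ± 2.36 against 1104 ± 63.7, Ly6c2 at 13.7 ± 3.47 against 1425 ± 99.8 and the formyl peptide receptor gene Fpr1 at 107 ± 16.7 against 6315 ± 216. Hsd11b1, whose enzyme regenerates active glucocorticoid, was lower (361-fold, counting interval 102 to 3050.5), and the T cell cytokine gene Il17a was 74.3-fold lower at 2.3 ± 2.02. Il12b was 3.85-fold higher at 7999.9 ± 508, Il23a 2.98-fold higher at 438 ± 65.2 and Il1b 2.92-fold higher at 84193 ± 5549. Nos2, Il6 and Tnf were chosen after their values were seen, and they were 13.9-fold, 2.58-fold and 1.58-fold lower, at 11002 ± 1764, 27787 ± 2898 and 106980 ± 2742. The calls of Il23a with a pseudocount of 0.1 (limma adjusted p = 0.222), of Il1b with robust variances (limma adjusted p = 0.0709) and of Tnf with quantile normalization (limma adjusted p = 0.163) were lost. The limma test called 3610 genes higher and 4033 lower, of which 1574 and 1599 differed at least 2-fold. With equal library totals the higher genes made up 73.5% of the calls, against 47.2%.

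Glycolysis was among the lists that were lower in the BHLHE40-Fl-labelled libraries with LPS, with 18 of the 23 tested members lower (19 adjusted over the list alone, limma camera test, adjusted p = 3.32e-16). In log2 differences Slc16a3 stood at -3.82, Pfkl at -3.34, Aldoc at -3.29 and the pyruvate dehydrogenase kinase gene Pdk1 at -2.69. Other targets of the hypoxia factor HIF-1 had 2 of the 20 tested members higher and 16 lower (2 and 16 adjusted over the list alone, limma camera test, adjusted p = 2.93e-08). The growth factor gene Vegfa stood at -2.70, the mitophagy gene Bnip3 at -3.19 and, against the list, the adrenomedullin gene Adm at 2.10. NADPH oxidase and antioxidant genes had 16 of the 19 tested members lower (16 adjusted over the list alone, limma camera test, adjusted p = 8.63e-11). The heme oxygenase gene Hmox1 stood at -3.44, Nqo1 at -2.23 and Prdx1 at -2.04. Lysosome and phagocytosis genes had 2 of the 27 tested members higher and 20 lower (2 and 23 adjusted over the list alone, limma camera test, adjusted p = 5e-11). The scavenger receptor gene Marco stood at -4.46, Stab1 at -2.60 and the complement gene C1qa at -3.55. LXR targets and lipid handling genes had 0 of the 18 tested members higher and 14 lower (1 and 14 adjusted over the list alone, limma camera test, adjusted p = 1.16e-06). The fatty acid binding protein gene Fabp4 stood at -1.89, Fabp5 at -1.02 and the cholesterol exporter gene Abca1 at -0.88. Inflammatory enzymes and mediators had 5 of the 22 tested members higher and 14 lower (7 and 15 adjusted over the list alone, limma camera test, adjusted p = 9.67e-05). Lcn2 stood at -4.83 and Saa3 at -4.28. In the same libraries the mitochondrial share of reads was 1.52%, against 0.562% in Lyz2Cre with LPS, and the median was -0.56 for general macrophage markers and 4.32 for mesothelial and stromal markers.

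Between genotype labels with LPS, cytokines and chemokines had members called in both directions and few interferon-stimulated genes were called. Cytokines had 6 of the 19 tested members higher and 7 lower (6 and 7 adjusted over the list alone, limma camera test, adjusted p = 0.761). In log2 differences Inhba stood at -3.44 and the interferon gene Ifnb1 at -2.79. Chemokines had 3 of the 22 tested members higher and 10 lower (3 and 11 adjusted over the list alone, limma camera test, adjusted p = 0.0301, and adjusted p = 0.126 with an estimated correlation), a call lost without Lyz2Cre LPS replicate 2 (adjusted p = 0.0508). Cxcl3 stood at -3.72 and Ccl6 at -2.84, whereas Ccl22 stood at 2.60 (limma adjusted p = 0.000466), a call lost with a pseudocount of 0.1 (limma adjusted p = 0.0707). Interferon-stimulated genes had 5 of the 44 tested members lower (3 adjusted over the list alone, limma camera test, adjusted p = 0.248). Their median of -0.23 turned to 0.14 under quantile normalization and 0.060 with equal library totals. Without Lyz2Cre control replicate 2 the list was called (adjusted p = 0.0477). Ifih1 stood at -0.60 and Gbp2 at -0.52, and both calls were lost with equal library totals (limma adjusted p = 0.108 and 0.129) and under quantile normalization (limma adjusted p = 0.164 and 0.915), where Gbp2 took the value 0.0255. Mesothelial and stromal markers had 16 of the 16 tested members higher (16 adjusted over the list alone, limma camera test, adjusted p = 1.57e-15). Upk3b stood at 444 ± 119 (SD, n = 3) and Krt19 at 186 ± 10.3 against 0.933 ± 1.62. General macrophage markers had 1 of the 15 tested members higher and 10 lower (1 and 10 adjusted over the list alone, limma camera test, adjusted p = 4.3e-06). Itgam stood at -3.12 and Aif1 at -3.69. T and NK cell markers had 1 of the 19 tested members higher and 14 lower (1 and 16 adjusted over the list alone, limma camera test, adjusted p = 0.00113). Cd3g stood at -4.36. Alternative activation genes had 5 of the 20 tested members higher and 8 lower (5 and 10 adjusted over the list alone, limma camera test, adjusted p = 0.234). Arg1 stood at -4.69.

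**Figure D4:**
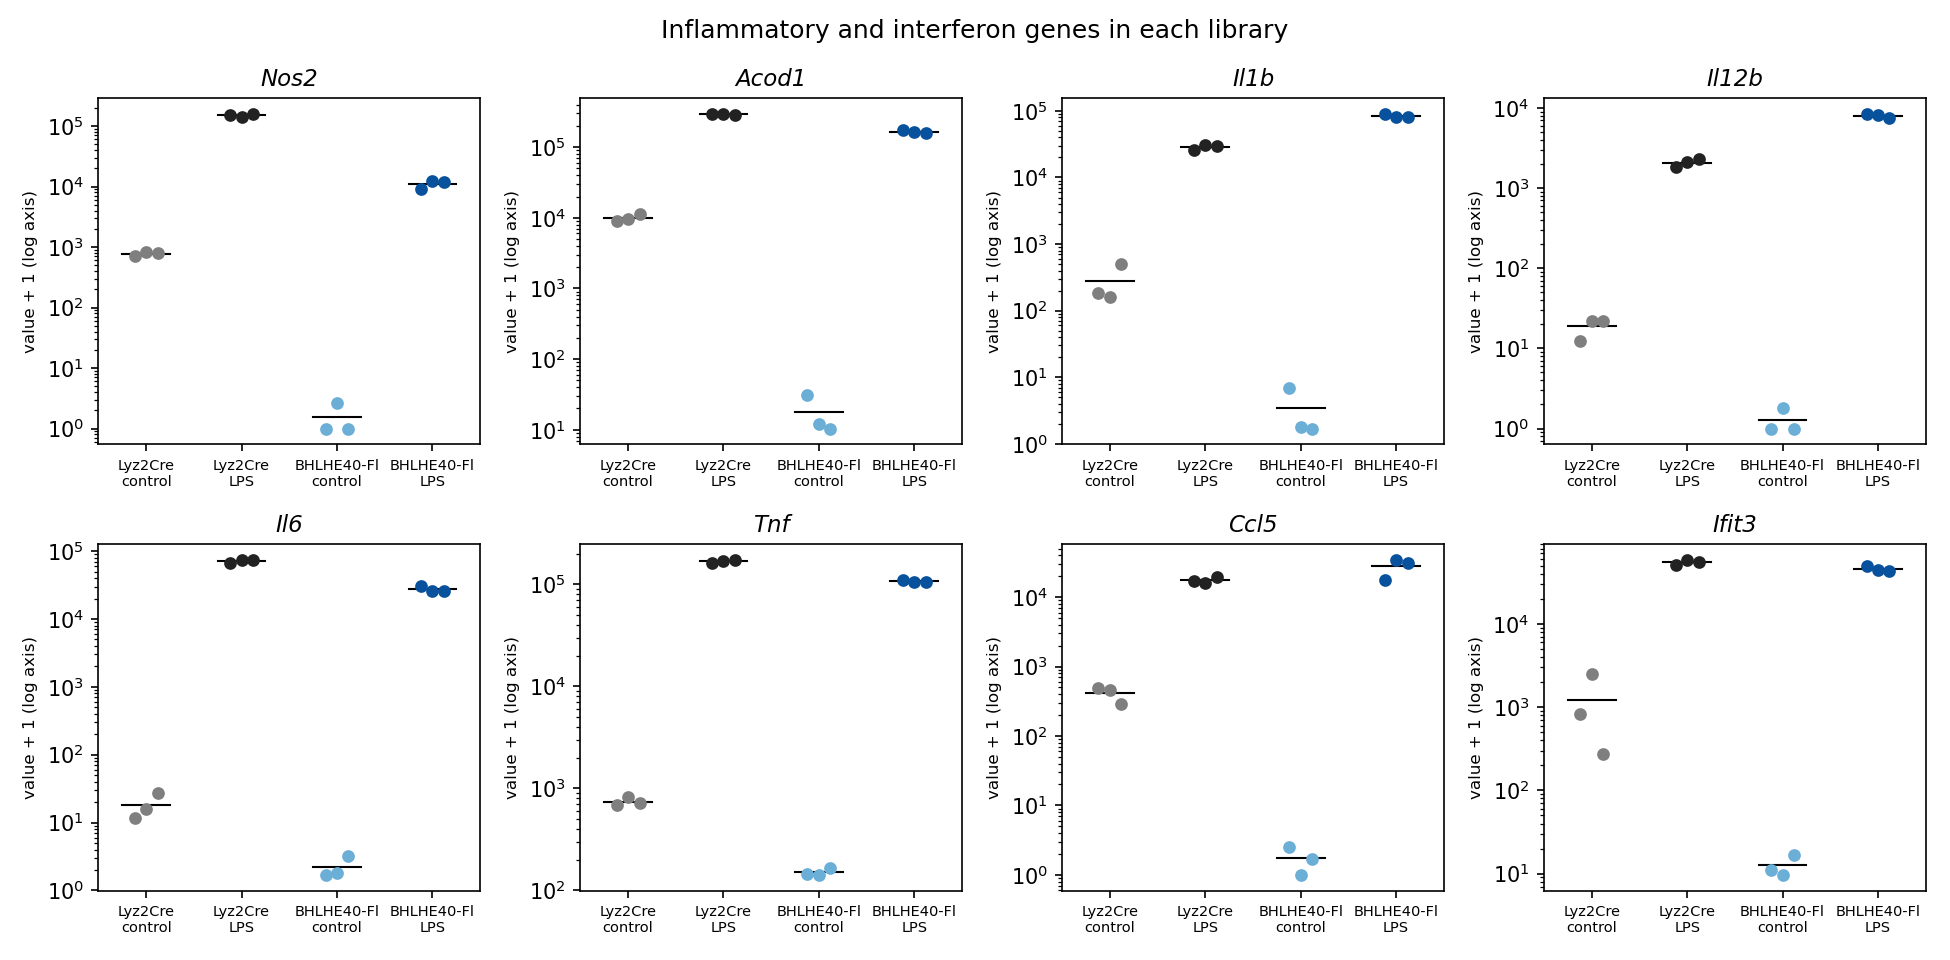
Deposited value + 1 on log axes of 8 inflammatory and interferon genes in each of the 12 libraries, where points are libraries and horizontal bars are group means (n = 3). In BHLHE40-Fl-labelled controls Nos2 lies between 0 and 1.6 before 1 is added, and with LPS between 8980 and 12224, against 143292 to 159928 in the Lyz2Cre libraries.

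The genotype comparisons share no libraries. Control and LPS comparisons both called 2077 genes lower and 1642 higher in the BHLHE40-Fl-labelled libraries, where independent lists would share 669 and 541, and called 418 in opposite directions. Across genes the log2 differences correlated with Pearson r = 0.660.

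The interaction tested whether the LPS effect differed between genotype labels, and for most inflammatory lists it was larger in the BHLHE40-Fl-labelled libraries, whose controls started lower. The log2 LPS effect of Ccl5 was larger by 8.57 ± 0.40 (SE), that of Acod1 by 8.45 ± 0.36, that of Il1b by 8.03 ± 0.58, that of Ccl22 by 7.72 ± 0.71 and that of Il12b by 5.85 ± 0.33, with limma adjusted p from 4.7e-11 for Acod1 to 3.86e-07 for Ccl22. The glutamate transporter gene Slc1a2 rose with LPS from 12.3 ± 2.89 to 1435 ± 45.8 in Lyz2Cre libraries (SD, n = 3) and from 12.7 ± 3.5 to 72.2 ± 2.59 in the others, an interaction of -4.33. Il10 rose from 5.87 ± 0.961 to 654 ± 197 and from 25.8 ± 9.36 to 140 ± 30, an interaction of -4.10. The cytokine gene Il1f6 (interaction -4.47) and the calcitonin receptor gene Calcr (-4.60) reached 33.3 ± 4.62 and 42.6 ± 2.93 in Lyz2Cre libraries with LPS, against 0.833 ± 0.723 and 0.933 ± 0.814, and the call of Calcr was lost with edgeR (adjusted p = 1). The limma test called 1944 genes with a higher and 1902 with a lower LPS effect in the BHLHE40-Fl-labelled libraries, of which 809 and 703 differed at least 2-fold. The higher ones made up 50.5% of the calls, 64.1% with equal library totals and 61.7% with edgeR. The mitochondrial share of reads also changed differently, from 1.13% to 0.562% with LPS in Lyz2Cre. In the BHLHE40-Fl-labelled libraries it was 1.36% in controls and 1.52% with LPS, where replicate 1 had 0.756%.

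Interferon-stimulated genes had 44 of the 44 tested members higher (44 adjusted over the list alone) for the interaction (limma camera test, adjusted p = 2.4e-36, and adjusted p = 0.104 with an estimated correlation). In log2 units of the interaction Ifit3 stood at 5.83, Ifi44 at 5.33 and Irf7 at 4.96. Inflammatory enzymes and mediators had 16 of the 22 tested members higher and 2 lower (17 and 2 adjusted over the list alone, limma camera test, adjusted p = 1.64e-17). Nos2 stood at 5.33 and Lcn2 at 5.11. Chemokines had 14 of the 22 tested members higher and 0 lower (14 and 1 adjusted over the list alone, limma camera test, adjusted p = 2.37e-13). Cxcl3 stood at 4.19 and Ccl9 at 4.07. Outside this list, the formyl peptide receptor gene Fpr2 stood at 5.74. Cytokines had 14 of the 19 tested members higher and 1 lower (14 and 1 adjusted over the list alone, limma camera test, adjusted p = 5.82e-13). The NF-kB list had 16 of the 22 tested members higher and 1 lower (16 and 1 adjusted over the list alone, limma camera test, adjusted p = 2.52e-11). Bcl3 stood at 2.10, Zfp36 at 1.65, Nfkbiz at 1.64 and Socs3 at 1.47. MHC class I presentation had 16 of the 18 tested members higher (16 adjusted over the list alone, limma camera test, adjusted p = 8.11e-15, and adjusted p = 0.093 with an estimated correlation). Nlrc5 stood at 2.34 and Tap1 at 2.05. Cholesterol synthesis had 19 of the 24 tested members higher (20 adjusted over the list alone, limma camera test, adjusted p = 2.66e-16). Lss and Stard4 had interactions of 1.27 and 1.42. The cell cycle list had 15 of the 34 tested members higher and 1 lower (15 and 2 adjusted over the list alone, limma camera test, adjusted p = 1.07e-05, and adjusted p = 0.115 with an estimated correlation). Ccne1 stood at 1.89, Mki67 at 1.65 and Ccna2 at 1.59. Bhlhe40 had an interaction of -0.81 (limma adjusted p = 8.45e-05), Lyz2 of 1.84 (limma adjusted p = 3.93e-07) and Bhlhe41 of -0.45 (limma adjusted p = 0.0685). The interaction of Bhlhe41 passed with array weights (limma adjusted p = 0.0487), in DESeq2 (adjusted p = 0.0475) and without Lyz2Cre LPS replicate 2 or BHLHE40-Fl-labelled LPS replicate 2 (limma adjusted p = 0.029 and 0.0274).

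Among the genes that LPS changed, effects that were smaller and effects that were larger in the BHLHE40-Fl-labelled libraries were both frequent. Of 2828 genes that LPS raised at least 2-fold in the mean of both genotype labels, 42.1% had a smaller LPS effect in the BHLHE40-Fl-labelled libraries, with a jackknife SE over libraries of 4.08 percentage points. The limma test called the effect larger for 698 of them and smaller for 352. In controls 1037 of these genes were lower in BHLHE40-Fl-labelled libraries and 352 higher, and with LPS 907 were lower and 457 higher. Of 3020 genes that LPS lowered, 43.8% had a smaller LPS effect in the BHLHE40-Fl-labelled libraries, with a jackknife SE of 3.50 percentage points, and 50.3% with equal library totals. Their effect was called larger for 435 and smaller for 231 by the limma test.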

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

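The tests of dilution, of LPS-like activation, of the Bhlhe40 transcript (both parts) and the spread of the re-labelled samples were chosen only after the result was seen, and the scaling test uses equal library totals, a setting chosen after seeing the data. The tests of both additional gene lists and the re-labelling itself were set out before.

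The LPS effect differed between genotype labels by the limma interaction test (adjusted p below 0.05) for 81 of the named genes. Of the cytokine and chemokine genes, the interaction (log2 LPS effect in the BHLHE40-Fl-labelled libraries minus that in Lyz2Cre) was 8.57 for Ccl5, 8.03 for Il1b, 7.72 for Ccl22, 5.85 for Il12b, 4.19 for Cxcl3, 3.91 for Il12a, 3.37 for Cxcl9 and 3.36 for Cxcl2. In the same set it was 3.36 for Inhba, 1.75 for Il23a, 1.64 for Tnf, 1.63 for Il6, 1.36 for Il27, 1.19 for Cxcl10, -2.10 for Ifnb1, -4.10 for Il10, 4.07 for Ccl9 and -4.47 for Il1f6. Among inflammatory enzymes, receptors and acute-phase genes it was 8.45 for Acod1, 5.74 for Fpr2, 5.33 for Nos2, 5.11 for Lcn2, 3.06 for Cd40 and 3.08 for Ly6c2. In the same set it was 2.67 for Orm1, 1.78 for Saa3, 2.21 for Hp, 3.14 for Fpr1, 2.99 for Marco and 2.18 for Tgm2. In the same set it was 1.13 for Cd14, 0.62 for Myd88, 1.84 for Lyz2, 0.81 for Adgre1 and 1.87 for Fcgr1. Among interferon-stimulated and MHC class I genes it was 5.83 for Ifit3, 5.33 for Ifi44, 4.86 for Mx1, 4.24 for Gbp5, 4.81 for Ifit2 and 2.34 for Rsad2. In the same set it was 2.34 for Nlrc5, 2.18 for Cmpk2, 2.10 for Gbp2, 2.05 for Tap1, 0.90 for Ifih1, 4.96 for Irf7 and 0.91 for H2-K1. Among NF-kB feedback and immediate early genes it was 3.08 for Nr4a3, 1.90 for Ier3, 1.64 for Nfkbiz, 1.47 for Socs3, 1.42 for Nfkbia, 2.10 for Bcl3, 1.65 for Zfp36 and 0.78 for Traf1. Among cell cycle and cholesterol genes it was 1.89 for Ccne1, 1.65 for Mki67, 1.59 for Ccna2, 0.51 for Mcm2 and -0.58 for Tpx2. In the same set it was 1.42 for Stard4, 1.20 for Sqle, 1.27 for Lss, 0.70 for Dhcr7 and 1.46 for Abca1. Among glycolysis, hypoxia, antioxidant and other genes it was -1.47 for Slc16a3, -1.25 for Pfkl, -1.40 for Pdk1, -0.61 for Vegfa, -1.14 for Bnip3, -0.85 for Hmox1 and -0.60 for Prdx1. In the same set it was -1.61 for Fabp4, -1.17 for Dbp, -1.23 for Cnr2, -1.97 for Rab7b, -1.10 for Cxcr4, -4.33 for Slc1a2, -4.60 for Calcr and -0.81 for Bhlhe40. Bhlhe40 RNA was not lower in the BHLHE40-Fl-labelled controls, which neither supports nor contradicts a partial deletion, so these directions are those of the labels. Of the 81 interaction calls, those of 5 genes were lost when single libraries were left out. The call of Dhcr7 was lost without Lyz2Cre control replicate 1 or 2 (limma adjusted p = 0.0733 and 0.0586), Lyz2Cre LPS replicate 1 or 2 (limma adjusted p = 0.0696 and 0.0811), BHLHE40-Fl-labelled control replicate 1 or 2 (limma adjusted p = 0.0688 and 0.0607) and BHLHE40-Fl-labelled LPS replicate 2 (limma adjusted p = 0.081). The call of Mcm2 was lost without Lyz2Cre control replicate 1 or 2 or 3 (limma adjusted p = 0.058, 0.0653 and 0.0559), Lyz2Cre LPS replicate 2 (limma adjusted p = 0.0867), BHLHE40-Fl-labelled control replicate 1 or 2 (limma adjusted p = 0.0719 and 0.0621) and BHLHE40-Fl-labelled LPS replicate 1 or 2 (limma adjusted p = 0.0688 and 0.0595). The call of Dbp was lost without Lyz2Cre control replicate 1 (limma adjusted p = 0.0993), Lyz2Cre LPS replicate 2 (limma adjusted p = 0.087), BHLHE40-Fl-labelled control replicate 1 or 2 or 3 (limma adjusted p = 0.0684, 0.0616 and 0.0827) and BHLHE40-Fl-labelled LPS replicate 3 (limma adjusted p = 0.0769). The call of Ifnb1 was lost without Lyz2Cre control replicate 1 or 3 (limma adjusted p = 0.098 and 0.0813), Lyz2Cre LPS replicate 2 or 3 (limma adjusted p = 0.115 and 0.0979), BHLHE40-Fl-labelled control replicate 1 or 2 or 3 (limma adjusted p = 0.0572, 0.0581 and 0.0636) and BHLHE40-Fl-labelled LPS replicate 1 or 2 or 3 (limma adjusted p = 0.0509, 0.0789 and 0.0924). The call of Il23a was lost without Lyz2Cre control replicate 1 (limma adjusted p = 0.0671), Lyz2Cre LPS replicate 1 or 2 (limma adjusted p = 0.0692 and 0.0599), BHLHE40-Fl-labelled control replicate 1 (limma adjusted p = 0.0541) and BHLHE40-Fl-labelled LPS replicate 2 or 3 (limma adjusted p = 0.0608 and 0.0849). The sign of Ifnb1 turned in edgeR (0.48) and DESeq2 (0.11). Calls ended by other settings were as follows. Robust variances ended those of Cxcl10, Ifih1 and Marco (limma adjusted p = 0.109, 0.0581 and 0.0649), a pseudocount of 5 that of Il6 (limma adjusted p = 0.278) and a pseudocount of 0.1 those of Marco, Ifnb1 and Il23a (limma adjusted p = 0.0624, 0.692 and 0.394). Quantile normalization ended those of Hmox1, Prdx1, Vegfa, Bnip3, Dhcr7, Mcm2 and Ifnb1 (limma adjusted p = 0.201, 0.142, 0.506, 0.0537, 0.113, 0.224 and 0.0625). Array weights and the replicate block ended that of Mcm2 (limma adjusted p = 0.0528 and 0.0555), and testing with no filter those of Ifnb1 and Il23a (limma adjusted p = 0.0745 and 0.0530). Equal library totals ended that of Ifnb1 (limma adjusted p = 0.113), edgeR those of Ifnb1, Il23a and Calcr (adjusted p = 0.681, 0.194 and 1), and DESeq2 those of Ifnb1 and Il23a (adjusted p = 0.972 and 0.214).

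The interaction was called by the limma camera test for 16 lists. The median interaction was 2.36 for interferon-stimulated genes, 1.79 for inflammatory enzymes and mediators, 1.63 for cytokines, 1.25 for chemokines, 0.996 for MHC class I presentation, 0.80 for cholesterol synthesis, 0.72 for the NF-kB list and 0.51 for the cell cycle. Of these calls, those for interferon-stimulated genes, MHC class I presentation and the cell cycle were lost with an estimated correlation (adjusted p = 0.104, 0.093 and 0.115). For immediate early genes it was 0.58 (adjusted p = 0.00032, and adjusted p = 0.093 with an estimated correlation), for small peritoneal macrophage and monocyte markers 0.44 (adjusted p = 0.00203, and adjusted p = 0.148 with an estimated correlation), for large peritoneal macrophage markers 0.27 (adjusted p = 0.0114, and adjusted p = 0.0582 with an estimated correlation) and for inflammasome and pyroptosis genes 0.13 (adjusted p = 0.000781, and adjusted p = 0.214 with an estimated correlation). For alternative activation it was 0.11 (adjusted p = 0.0408, and adjusted p = 0.108 with an estimated correlation), a call lost without Lyz2Cre LPS replicate 3 or without BHLHE40-Fl-labelled control replicate 2 or LPS replicate 1 (adjusted p = 0.0542, 0.0665 and 0.0535) or with a pseudocount of 0.1 (adjusted p = 0.0508). For glycolysis it was -0.14, or 0.057 under quantile normalization (adjusted p = 0.0407, and adjusted p = 0.209 with an estimated correlation), a call lost without Lyz2Cre control replicate 2, Lyz2Cre LPS replicate 2 or 3, or BHLHE40-Fl-labelled control replicate 2 (adjusted p = 0.0505, 0.0574, 0.0513 and 0.0848), and with equal library totals (adjusted p = 0.11). For lysosome and phagocytosis genes it was -0.27 (adjusted p = 0.0169, and adjusted p = 0.394 with an estimated correlation), a call lost without Lyz2Cre control replicate 3 (adjusted p = 0.0559) and with equal library totals (adjusted p = 0.0799). Its mean of -0.032 became 0.00996 and 0.0853 there. For mesothelial and stromal markers it was -0.55 (adjusted p = 0.0464, and adjusted p = 0.388 with an estimated correlation), and that call was lost without Lyz2Cre control replicate 1 or 3, Lyz2Cre LPS replicate 2, or BHLHE40-Fl-labelled control replicate 2 or 3 (adjusted p = 0.0598, 0.0625, 0.0682, 0.0665 and 0.0902). It was also lost without BHLHE40-Fl-labelled LPS replicate 1 or 2 (adjusted p = 0.112 and 0.056) or with a pseudocount of 0.1 (adjusted p = 0.118).

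Upk3b, Lrrn4 and other genes of mesothelium, the lining of the abdominal cavity, were detected in the BHLHE40-Fl-labelled libraries, where Upk3b was at 629 and Krt19 at 175 in controls. Of a second list of mesothelial genes, 91.7% were called higher in these controls (11 of 12, with Rarres2 lower), and 5 of the 12 had a mean of at least 10 in Lyz2Cre controls. Plxna4 was at 871 in BHLHE40-Fl-labelled and 104 in Lyz2Cre controls, and Tgm1 at 290.0 and 126. Of a list of epithelial genes that mesothelium does not use, 7.14% of 14 were called higher, which argues against a general loss of silencing of epithelial genes in the macrophages. Mesothelial cells among the collected cells are a candidate source of this RNA, and no sort or gate is given in the labels. Whether the genotype or the collection brought them in was not tested.

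Inflammatory and interferon genes were lower in the BHLHE40-Fl-labelled controls. Of the 15 general macrophage markers, 53.3% (8) lay above every interferon-stimulated gene by more than 2 standard errors, among them Mpeg1 at 0.19 and Tyrobp at -0.06, which argues against dilution by mesothelial or other non-myeloid cells as the whole cause, although Itgam, Adgre1 and Aif1 stood at -3.04, -2.43 and -4.44. With equal library totals 100% of the 44 interferon-stimulated genes stayed lower. That setting moved the median log2 difference of all genes in controls from 0.00 to 0.17, while the highest of the 44 stood at -1.12 as deposited. A shift of that size could not have turned any of them, so the outcome was fixed by these sizes. It shows only that their lower values do not depend on the choice between these scalings. The mean LPS effect and the genotype difference in controls, which share control libraries, had a Spearman rho of -0.35 and a covariance of -1.02 across 2828 LPS-raised genes (not independent replicates), where 1000 simulations without a genotype difference gave medians of -0.015 (95% of them from -0.163 to 0.199) and -0.0082. The BHLHE40-Fl-labelled controls enter these 2 measures with opposite signs, so a difference confined to those controls would itself lower the correlation. The simulations held no such difference and cover only the spread between replicates, so the gap does not single out an LPS-like pattern. An LPS-like activation of the Lyz2Cre controls and a difference of genotype also cannot be told apart because each genotype label has its own controls.

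Bhlhe40 RNA was not lower in the BHLHE40-Fl-labelled controls. Its log2 difference of 0.67 ± 0.08 (SE) shows that the transcript was not lost from these libraries as a whole, which restates the observation. Loss in the macrophages alone cannot be judged from it. The value is not split by cell type, and these libraries had higher mesothelial and lower general macrophage markers. At 158.6% of the Lyz2Cre level, a deletion of some exons with the remaining transcript still counted cannot be told apart from an intact gene, because the table holds 1 value per gene.

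The real grouping was set against other splits of the same libraries. For LPS in Lyz2Cre the real split called 9977 genes and the highest of the others 0, for LPS in Lyz2Cre-BHLHE40-Fl 10320 and 1, for genotype in controls 6445 and 1, and for genotype with LPS 7643 and 0. In each of these, 10 splits are too few for a share under 0.05. For the interaction, 1 of 100 re-labellings of genotype within treatment, out of 200 possible, gave as many genes, the real one with 3846 against 2730 for the highest other. For the share of LPS-raised genes with a smaller LPS effect, 74 of 100 re-labellings lay as far from an even split as the real 42.1%, the most distant at 30.4%, and for LPS-lowered genes 8 of 100 did, against the real 43.8% and the most distant 57.7%. Labellings that mix the genotypes carry their differences as spread, with a median residual SD of 0.534 on the log2 scale against 0.302 for the real one. Only 6 of the other labellings drawn stayed within 1.5 times the real SD, and these were not compared on their own. Whether chance can be excluded therefore stays open for these 3 results.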

How the results depend on the processing

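Chosen only after seeing the data were equal library totals, the mean of at least 50, and the edgeR and DESeq2 tests. For 230 named gene and contrast pairs, 3092 of 3134 values over the settings kept direction and side of the threshold, while 33 lost the call, 3 gained it and 6 reversed. With single libraries left out, 2714 of 2760 did so, 44 lost the call and 2 gained it. Of the genes called by limma, 0 were called in the opposite direction by edgeR or DESeq2. Equal library totals turned 1042 for LPS in Lyz2Cre and 742 for LPS in Lyz2Cre-BHLHE40-Fl, and quantile normalization 339 and 236, with 1 for genotype with LPS and 1 for the interaction. Bhlhe40 in controls ranged from 0.63 to 0.94 over the settings.

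With equal library totals, genes called higher and lower were 2395 and 9498 for LPS in Lyz2Cre, 2619 and 9556 for LPS in Lyz2Cre-BHLHE40-Fl, 5099 and 2526 for genotype in controls and 6206 and 2238 with LPS. This setting rescales each library by its total, which differed between groups. With a minimum log2 change of 1 they were 2760 and 2598, 2673 and 2939, 1608 and 1509, 1574 and 1599, and 809 and 703 for the interaction, since a stricter threshold keeps fewer genes.

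The share of LPS-raised genes with a smaller LPS effect was 35.2% with edgeR, 32.8% with equal library totals and 37.0% with the mean of at least 50. For LPS-lowered genes it was 48.8% with edgeR and turned to 50.3% with equal library totals. The cause was not tested. Leaving out single libraries gave 40.9% to 44.3% and 42.7% to 46.0%.

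Of the 87 list calls 36 held with an estimated correlation, which replaces the preset one. The fry test called 132, since it does not compare a list with other genes. Equal library totals gave 83, of which 76 were shared, and a left-out library 82 to 87, with 0 turned. Oxidative phosphorylation turned with equal library totals to a mean of -0.51 for LPS in Lyz2Cre and -0.39 in Lyz2Cre-BHLHE40-Fl. For alternative activation under LPS in Lyz2Cre (mean 0.45) and NADPH oxidase and antioxidant genes under LPS in Lyz2Cre-BHLHE40-Fl (mean 0.12) the direction was up in the fry test and down in the camera test, which called neither (adjusted p = 0.934 and 0.978), and the means are the same in both.

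Lyz2 for LPS in Lyz2Cre turned to -0.38 with equal library totals. Gbp2 with LPS turned to 0.0255 under quantile normalization, and Bhlhe40 with LPS to 0.00353 under quantile normalization and 0.14 with equal library totals. The Ifnb1 interaction turned to 0.48 with edgeR and 0.11 with DESeq2. The cause was not tested.

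The replicate block gave 5030 higher and 4785 lower, 4958 and 5125, 2896 and 3225, 3474 and 3893, and 1824 and 1704, in the same order. Deviations of 18 same-numbered pairs correlated from -0.066 to 0.028, 0 of them above 0.1, so numbers are not taken to pair samples. In reads, depth limits statements on genes at 0, where a floor of 3 reads over the group holds.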

Other observations

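The list of IL-17-producing T cell genes was chosen only after the values of Il17a and Il22 were seen, and its genes are described here with no explanation. Il17a, the cytokine gene of these cells, stood at 57.5 ± 17.4 in Lyz2Cre controls and 171 ± 11 with LPS (SD, n = 3), and at 0 ± 0 and 2.3 ± 2.02 in BHLHE40-Fl-labelled libraries. Il22 stood at 80.8 ± 7.8 with LPS in Lyz2Cre and at 9.77 ± 3.86 in the others, and the receptor gene Il23r at 489.8 ± 20.4 and 87.4 ± 12. Trdc, a T cell receptor delta constant gene, stood at 36.3 ± 2.31 in Lyz2Cre controls and 0.467 ± 0.808 in BHLHE40-Fl-labelled controls. Of 12 genes, 7 were called lower and 1 higher in BHLHE40-Fl-labelled controls (7 and 1 adjusted over the list alone), and 10 lower and 1 higher with LPS (10 and 1 adjusted over the list alone). The higher one, Il1r1, stood at 289 ± 20.7 against 124 ± 4.31 in controls. Of the 12, 7 had a mean of at least 10 in Lyz2Cre controls and 2 are also in other lists.

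Other lists fixed in advance also moved with LPS. Genes of IL-10 and the restraint of inflammation had 11 of the 18 tested members higher and 3 lower (11 and 4 adjusted over the list alone) in Lyz2Cre (limma camera test, adjusted p = 0.00154, and adjusted p = 0.117 with an estimated correlation) and 12 of the 18 tested members higher and 4 lower (13 and 4 adjusted over the list alone) in the BHLHE40-Fl-labelled libraries (limma camera test, adjusted p = 0.00212, and adjusted p = 0.121 with an estimated correlation). Inflammasome and pyroptosis genes had 12 of the 18 tested members higher and 3 lower (12 and 3 adjusted over the list alone, limma camera test, adjusted p = 2.31e-05, and adjusted p = 0.126 with an estimated correlation) and 13 of the 18 tested members higher and 4 lower (13 and 4 adjusted over the list alone, limma camera test, adjusted p = 5.98e-06, and adjusted p = 0.116 with an estimated correlation).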
